A study of Drosophila melanogaster with 14 samples.

How the data were processed

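RNA of whole larvae was measured in 14 samples of 4 genotypes by bulk sequencing of polyadenylated RNA. The table deposited by the authors holds log2 CPM values, read counts per gene relative to library size on a log2 scale, scaled between libraries by the TMM method per the labels of the series. FastQC 0.11.9, cutadapt 3.5, STAR 2.7.11b and edgeR 3.40 and the builds BDGP6 and dm6 are named in the submitters' processing notes. How reads were assigned to genes, and whether strand was used, is not given in the sources used here, so overlapping or antisense genes and near-identical copies can share reads. Per the labels of the series the authors tested counts with quasi-likelihood tests; the table used here is on a log scale, so limma was used. Flies were reared at 25 degrees C per the labels' protocols. The sample labels name larvae of the last instar, whereas the protocol text mentions adult flies, and marker levels for both stages are given with the results. All value columns of the table were matched to a sample.

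Each deposited log2 value, taken back to the linear scale less the floor of the table (-3.65 log2 CPM, 0.0797 CPM), was a whole multiple of the value of 1 read in its library, for 100% of 250166 values within a tolerance of 0.01 reads. This gave the reads per library and showed a count of 2.00 reads on average, added by the authors in proportion to library size before taking logs. Fold changes of low genes are therefore pulled towards 0. Intervals on reads cover counting error only. Gene positions are from Ensembl release 115 of BDGP6, a build named in the processing notes, and were found for 17790 of 17869 genes.

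Genes with more than 0 log2 CPM in at least 3 libraries were tested with limma 3.58.1 in R 4.3.3, with genotype as the single term, all 14 libraries in 1 fit, and variances moderated with an intensity trend and robust shrinkage. Adjusted p-values are Benjamini-Hochberg values within a comparison, with 0.05 as the threshold, and every adjusted p printed for a gene is from limma. The 7 comparisons were 3 mutants against the control, 3 between mutants, and the interaction, which is the double mutant minus both single mutants plus the control. Values given with a gene are log2 fold changes, and standard errors are those of the moderated fit. Nothing in the labels says that the samples of a genotype came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical. Libraries of a genotype differed by more than sampling noise, with a chi-square per degree of freedom of 27.2 to 323. Before the data were examined, 37 gene lists, the tests and most alternatives were fixed. Lists were tested with camera at a preset correlation of 0.01 between genes and again with the correlation estimated, with which no list passed the threshold. Ranges of an adjusted p over the alternatives leave out the estimated correlation, which is given beside. Of their members 821 were matched to the table and 4 were not. Counts of list members use the adjustment over all tested genes unless said to be adjusted over the list alone.

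Genes named in the text follow a rule fixed with the lists. The septins and w are named always. Otherwise they are the genes with the largest log2 fold changes in each direction among called genes with a mean of at least 2 log2 CPM and no overlap between both groups (12 for the double mutant against the control, 6 for each single mutant, 5 for the other comparisons, the interaction without the overlap condition), and up to 4 members of each list with the smallest adjusted p. The fit was tested on simulated reads at the depths of the 14 libraries, over 12410 genes with 100 changed 2-fold and as many 4-fold. Of genes changed 2-fold against the control, 73% were recovered in the double, 60% in the Sep2 and 54% in the Sep5 mutant. In the interaction it was 18%. Of those changed 4-fold, 100%, 99%, 100% and 95% were, and 13, 7, 7 and 3 unchanged genes were called. All genes had the same spread (dispersion 0.0521), so recovery at the real libraries' spread was not tested. Alternatives covered the filter, an added 1 CPM, quantile normalization, centring on the median, the variance model, sample weights, voom on the recovered reads, the libraries in the fit, a replicate block, a 2-fold minimum and the omission of each library. Double mutant libraries 1 and 2 alone and the centring of list tests were added after the data were seen. Groups share replicate numbers in the labels, which name no common animal, batch or day. Deviations of same-numbered libraries from their group means correlated at 0.166 to 0.452 in the 3 pairs of control and Sep2 mutant, all above 0.1, which was so in no other pair of groups. From these correlations alone the numbers were taken to pair the control with the Sep2 mutant, and the value with the replicate as a block is given there, and in the interaction, which takes in both, where it changes a call. Figures were drawn with matplotlib 3.10.9.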

Results

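Polyadenylated RNA was sequenced in bulk from whole larvae of Drosophila melanogaster mutant in Sep2, in Sep5 or in both, and from a control stock. Septins are GTP-binding proteins that assemble into filaments at membranes and along the cytoskeleton, and the title of the study places them at the neuromuscular junction and in the organization of microtubules. Of the 14 libraries, 4 came from the white-eyed control stock w1118, 3 from the Sep2 mutant, 3 from the Sep5 mutant and 4 from the double mutant, which the series text calls homozygous. Reads per library ranged from 8858393 in double mutant replicate 3 to 47203028 in Sep5 mutant replicate 2. The mitochondrial large ribosomal RNA took 10.6% to 24.9% of the reads in the double mutant, 4.74% to 9.83% in the control, 5.74% to 7.25% in the Sep2 mutant and 6.70% to 11.8% in the Sep5 mutant. Nuclear ribosomal RNA took 1.37% to 2.61% in the Sep2 mutant, 0.432% to 1.17% in the control, 0.706% to 1.57% in the Sep5 mutant and 0.171% to 1.89% in the double mutant. Scaling factors behind the deposited values were 0.799 to 0.843 in the double mutant and 1.08 to 1.22 in the control. Of 17869 genes in the table, 12586 were tested. Markers of the adult stage, such as yolk protein, chorion and opsin genes, had group medians from -2.49 log2 CPM in the control to -1.86 in the double mutant. Medians of the larval salivary glue proteins lay between 7.59 and 10.14 log2 CPM.

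The mutated genes were examined first. Septin5 (chromosome 2R, 7960133 to 7961921), the target in the Sep5 mutant, had 2 reads over the 3 Sep5 mutant libraries against 656 over the 4 control libraries. This is 0.483% of the control rate (95% exact counting interval 0.0584% to 1.75%). The double mutant had 34 Septin5 reads, 8.19% of the control rate (5.62% to 11.6%). Septin5 was higher in the double than in the Sep5 mutant (2.31, SE 0.56, adjusted p = 0.0207). The call was lost without double mutant replicate 4 (0.0542) or Sep5 mutant replicates 2 (0.0797) and 3 (0.0610), and without a filter (0.0562), with 1 CPM added (0.171), by voom (0.0567), with only the libraries of both groups (0.111) and with double mutant libraries 1 and 2 alone (0.141). Its adjusted p lay at 0.00667 to 0.171 over the alternatives. Septin2 (chromosome 3R, 20586129 to 20588356) averaged 55.4 CPM (SD 9.68, n = 4) in the control. It averaged 61.7 CPM (SD 15.6, n = 3) in the Sep5 mutant and 25.8 CPM (SD 3.87, n = 3) in the Sep2 mutant. Its highest value in the Sep2 mutant, 29.5 CPM, lay under the lowest control value of 46.7 CPM, and the difference did not pass the test (log2 fold change -1.09, SE 0.76, adjusted p = 0.410). The SD of log2 CPM was 0.25 in the control, 0.22 in the Sep2 mutant and 2.05 in the double mutant, whose spread enters the shared fit. The difference passed with sample weights (0.0229), with only the libraries of both groups (0.0121), with double mutant libraries 1 and 2 alone (0.0462) and without double mutant replicate 4 (0.0417), within an adjusted p of 0.0121 to 0.580 over the alternatives. In the double mutant Septin2 stood at 0.805, 0.350 and 0.749 CPM in replicates 1 to 3 and at 9.19 CPM, from 160 reads, in replicate 4. It fell against the control (-5.54, SE 0.70, adjusted p = 6.87e-05), and by a log2 fold change of -6.52 without replicate 4. The labels do not say what the Sep2 allele removes, so remaining transcript does not speak against a label, and related septins can share reads. Of the other septins, pnut (-0.73, SE 0.19, adjusted p = 0.00741) and Septin1 (-0.73, SE 0.22, adjusted p = 0.0143) fell in the double mutant. Septin1 was not called with double mutant libraries 1 and 2 alone (0.142, within 0.00505 to 0.142 over the alternatives), and Septin4 stood at -0.20, SE 0.18, adjusted p = 0.404. The eye colour gene w, which many transgenes carry as a marker, rose in the double mutant (2.08, SE 0.43, adjusted p = 0.00162) and in the Sep5 mutant (1.86, SE 0.46, adjusted p = 0.0308). It stood at -1.05, SE 0.46, adjusted p = 0.207 in the Sep2 mutant, and was called with sample weights (0.0104), within 0.0104 to 0.418 over the alternatives. The call for w in the Sep5 mutant was lost without control replicates 1 (0.0939), 2 (0.0584) and 4 (0.0515) or Sep5 mutant replicates 1 (0.117), 2 (0.0514) and 3 (0.0707), and without a filter (0.0840) and with sample weights (0.0574). It lay at an adjusted p of 0.00364 to 0.117 over the alternatives.

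**Figure D1:**
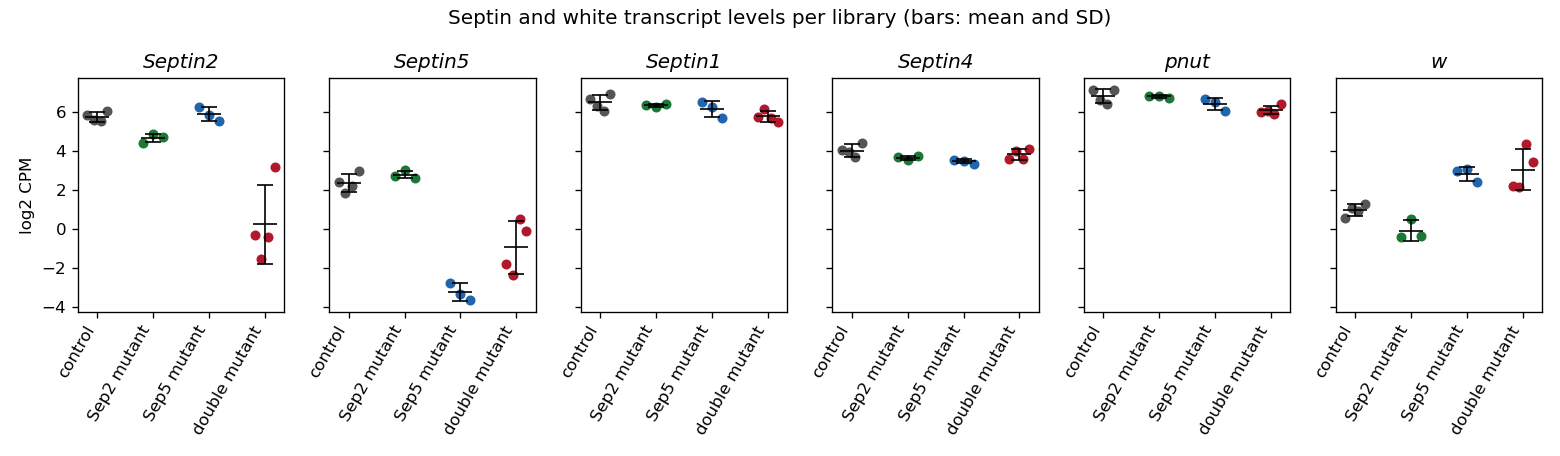
Level of 5 septin genes and of w in each of the 14 libraries in log2 CPM, by genotype; points are libraries and bars give the mean and SD. Septin5 lies lowest in the Sep5 mutant, and Septin2 lies lowest in the double mutant, where replicate 4 reaches 3.20.

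The comparison of the double mutant with the control asked what changes when both septins are mutated. The ecdysone response genes br, which encodes a transcription factor of the early hormone response (log2 fold change -2.54, SE 0.26, adjusted p = 1.30e-05), ImpE1 (-3.53) and ImpE2 (-5.28) and the transporter gene E23 (-3.57) fell. The sarcomere genes Tm2, which encodes a tropomyosin (1.92, SE 0.33, adjusted p = 0.000542), Mlp60A, a muscle LIM protein gene (2.21), up, a troponin T gene (2.08), and Zasp52 (1.34) rose. The respiratory genes RFeSP (1.46), COX5B (1.41) and Cyt-c1 (1.53) and the glycolytic genes Gpdh1 (2.35), Tpi (1.43) and Gapdh1 (1.35) rose. The cyclin genes CycB (-1.05), CycB3 (-1.09) and CycA (-0.80) and the mitotic kinase gene polo (-0.90) fell. Each gene of this paragraph kept its limma call in every run that left out one library. In all, 5658 of 12586 genes changed, 2832 higher and 2826 lower, and 3515 of them by at least 2-fold. The share higher was 50.1%, and 45.0% to 53.4% over the alternatives.

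Among the named genes, the largest increases were in the lysozyme genes LysD (chromosome 3L, 1210717 to 1211196), which rose by a log2 fold change of 10.19, SE 0.77, adjusted p = 2.33e-06, and LysC, by 9.60. Their neighbours LysB and LysE rose by 6.07 and 5.82. These copies are alike enough that the share of reads of each one is uncertain. The cytochrome P450 gene Cyp6a17 (chromosome 2R, 14873953 to 14875739) rose by 8.57, SE 0.57, adjusted p = 4.48e-07, with 3 reads or fewer in 2 of the 4 control libraries. Increases were also found in CG13461 (8.00) and CG15534 (6.87) and in the salivary gland gene ng2 (5.58). Without control replicate 4 the log2 fold change was 11.20 for LysD, 10.65 for LysC, 9.32 for Cyp6a17 and 8.91 for CG13461, and without control replicate 2 it was 9.48 for LysD and 8.90 for LysC. The genes CG3819 (5.12), CG5810 (4.99) and CG7881 (4.90) rose, and the tyrosine breakdown gene hgo rose 36.8-fold. The largest decreases were in CG34193 (-8.90), the drosomycin-like gene Drsl2 (-8.09, SE 0.96, adjusted p = 5.09e-05), CG7906 (-7.87) and Achl (-7.81) and the alkaline phosphatase gene Alp7 (-7.75). They were followed by CG7924 (-7.55), CG34296 (-7.24), CG14664 (-7.22), CG3397 (-6.62) and CG13606 (-6.53), the transcription factor gene slbo (-6.50) and CG11892 (-6.09). Without double mutant replicate 4 the log2 fold change was -8.07 for CG3397 and -7.02 for CG11892. CG34193, Drsl2 and CG34296 had 3 reads or fewer in 3 of the 4 double mutant libraries, so the size of their change depends on the count the authors added before taking logs. CG34193 was not called by voom on recovered reads (0.0525, within 4.73e-06 to 0.0525 over the alternatives). CG14664 was not called by voom (0.0780) or with double mutant libraries 1 and 2 alone (0.0779, within 3.33e-07 to 0.0780 over the alternatives). CG7924 was not called with those libraries alone (0.0614, within 4.31e-05 to 0.0614 over the alternatives).

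**Figure D2:**
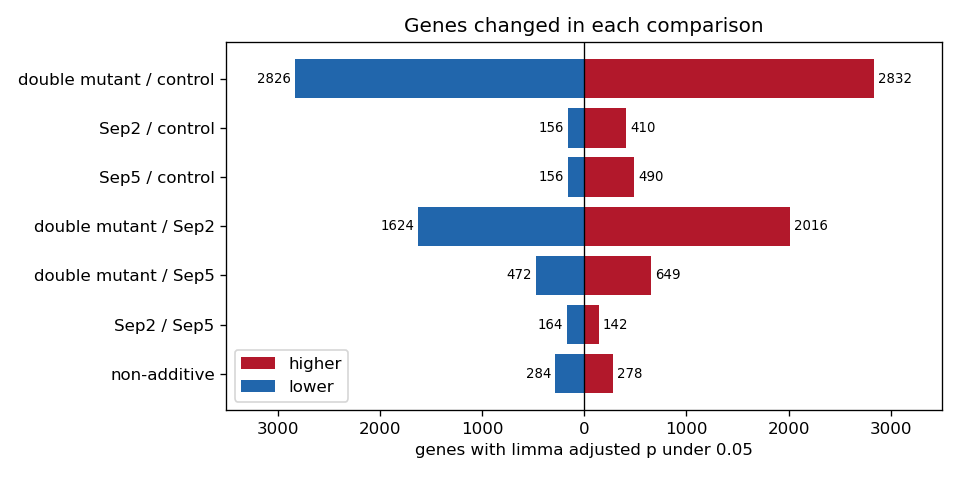
Number of genes past the limma threshold in each comparison, higher to the right and lower to the left. The double mutant against the control has 2832 higher and 2826 lower genes, and the Sep2 against the Sep5 mutant has 142 and 164.

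Oxidative phosphorylation was called higher in the double mutant, with 57 of 83 tested members higher and 7 lower (57 and 9 adjusted over the list alone, camera adjusted p = 6.79e-06). The muscle sarcomere was called higher, with 17 of 22 tested members higher and 0 lower (17 and 0 adjusted over the list alone, camera adjusted p = 1.58e-05). Glycolysis was called higher, with 10 of 13 tested members higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 0.000223). Mitochondrial ribosomal proteins were called higher, with 21 of 72 tested members higher and 0 lower (13 and 0 adjusted over the list alone, camera adjusted p = 0.000290). Digestive enzymes were called higher, with 29 of 46 tested members higher and 7 lower (31 and 8 adjusted over the list alone, camera adjusted p = 1.24e-05). Detoxification enzymes were called higher, with 12 of 18 tested members higher and 1 lower (14 and 1 adjusted over the list alone, camera adjusted p = 7.60e-05). With an estimated correlation the adjusted p was 0.719 for each of these 6 lists. The detoxification genes Cyp12d1-p (3.45), Cyp6w1 (3.89) and GstE1 (3.20) rose, and the P450 gene Cyp6d5 fell (-1.63). Cytosolic ribosomal proteins were called higher, with 37 of 91 tested members higher and 2 lower (39 and 2 adjusted over the list alone, camera adjusted p = 6.79e-06). Their adjusted p was 0.791 with an estimated correlation and 0.564 after quantile normalization, within 2.21e-10 to 0.564 over the alternatives. The mitochondrial large ribosomal RNA, which also differed between these genotypes, took a mean of 18.4% of the reads in the double mutant (SD 6.59, n = 4). Its mean in the control was 7.99% (SD 2.31, n = 4).

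Proteasome subunits were called lower in the double mutant, with 0 of 30 tested members higher and 21 lower (0 and 24 adjusted over the list alone, camera adjusted p = 9.01e-06). The regulatory subunit genes Rpn6 (-0.93) and Rpn10 (-0.83) were among those that fell. The ecdysone response was called lower, with 2 of 20 tested members higher and 14 lower (2 and 14 adjusted over the list alone, camera adjusted p = 0.000223). Cell cycle and DNA replication was called lower, with 1 of 24 tested members higher and 10 lower (1 and 10 adjusted over the list alone, camera adjusted p = 0.0139). The septins were called lower, with 0 of 5 tested members higher and 4 lower (0 and 4 adjusted over the list alone, camera adjusted p = 0.0139). Septin2 and Septin5, the mutated genes themselves, were among the lower members, with pnut and Septin1. The adjusted p with an estimated correlation was 0.719 for these 4 lists. Male germline markers were called lower, with 0 of 20 tested members higher and 9 lower (0 and 9 adjusted over the list alone, camera adjusted p = 0.0128). Their adjusted p was 0.803 with an estimated correlation, and betaTub85D (-1.52) and Mst98Ca (-1.43) fell. Male germline markers were not called without double mutant replicate 2 (0.0577), within an adjusted p of 0.00150 to 0.0577 over the alternatives. Lipid storage and synthesis was called higher, with 8 of 13 tested members higher and 1 lower (8 and 1 adjusted over the list alone, camera adjusted p = 0.0474). Its adjusted p was 0.719 with an estimated correlation, and AkhR, the receptor gene of adipokinetic hormone, rose (1.67). Lipid storage and synthesis was not called without control replicates 2 (0.0881) and 3 (0.0584) or double mutant replicates 2 (0.0537) and 4 (0.106), nor under the stricter filter (0.0807), after quantile normalization (0.0883), after centring on the median (0.0549) or with double mutant libraries 1 and 2 alone (0.0748), within an adjusted p of 0.0269 to 0.106 over the alternatives. These lists moved with the same difference in mitochondrial ribosomal RNA.

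Salivary gland transcripts went both ways in the double mutant. The new-glue genes ng1 (4.21), ng2 (5.58) and ng3 (2.87) rose and Sgs5bis fell (-3.34). Salivary glue proteins were not called, with 3 of 10 tested members higher and 6 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.735). Among neuromuscular genes, Syt4, a synaptotagmin used in retrograde signalling from muscle, rose (1.62, SE 0.19, adjusted p = 3.80e-05). The glutamate receptor subunit genes GluRIIE (1.47) and GluRIIC (1.29), the scaffold gene metro (1.11) and the receptor auxiliary gene Neto (1.04) rose. The postsynaptic list was not called, with 4 of 24 tested members higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.251). The presynaptic list was not called, with 2 of 27 tested members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.581). Of the microtubule genes, tau rose by 2.36, SE 0.28, adjusted p = 3.74e-05, ringer by 2.03 and CLIP-190 by 1.14. The stathmin gene stai fell (-1.41, SE 0.23, adjusted p = 0.000335). Microtubule-associated proteins and motors were not called, with 4 of 29 tested members higher and 6 lower (3 and 6 adjusted over the list alone, camera adjusted p = 0.776). The tubulin genes alphaTub85E (1.89) and betaTub97EF (1.98) rose and alphaTub84D fell (-0.67). Tubulins were not called, with 3 of 6 tested members higher and 1 lower (3 and 1 adjusted over the list alone, camera adjusted p = 0.372). The median of the tubulin list changed sign under quantile normalization. In cytokinesis, the citron kinase gene sti (-0.83), Klp3A (-1.02) and the anillin gene scra (-0.70) fell, and tum rose (0.74). Cytokinesis was not called, with 1 of 17 tested members higher and 8 lower (1 and 8 adjusted over the list alone, camera adjusted p = 0.0955). The cytokinesis list was called after quantile normalization (0.0427) and without double mutant replicate 4 (0.0382), within an adjusted p of 0.0382 to 0.208 over the alternatives. Sgs5bis, Neto and tum were not called with double mutant libraries 1 and 2 alone.

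**Figure D3:**
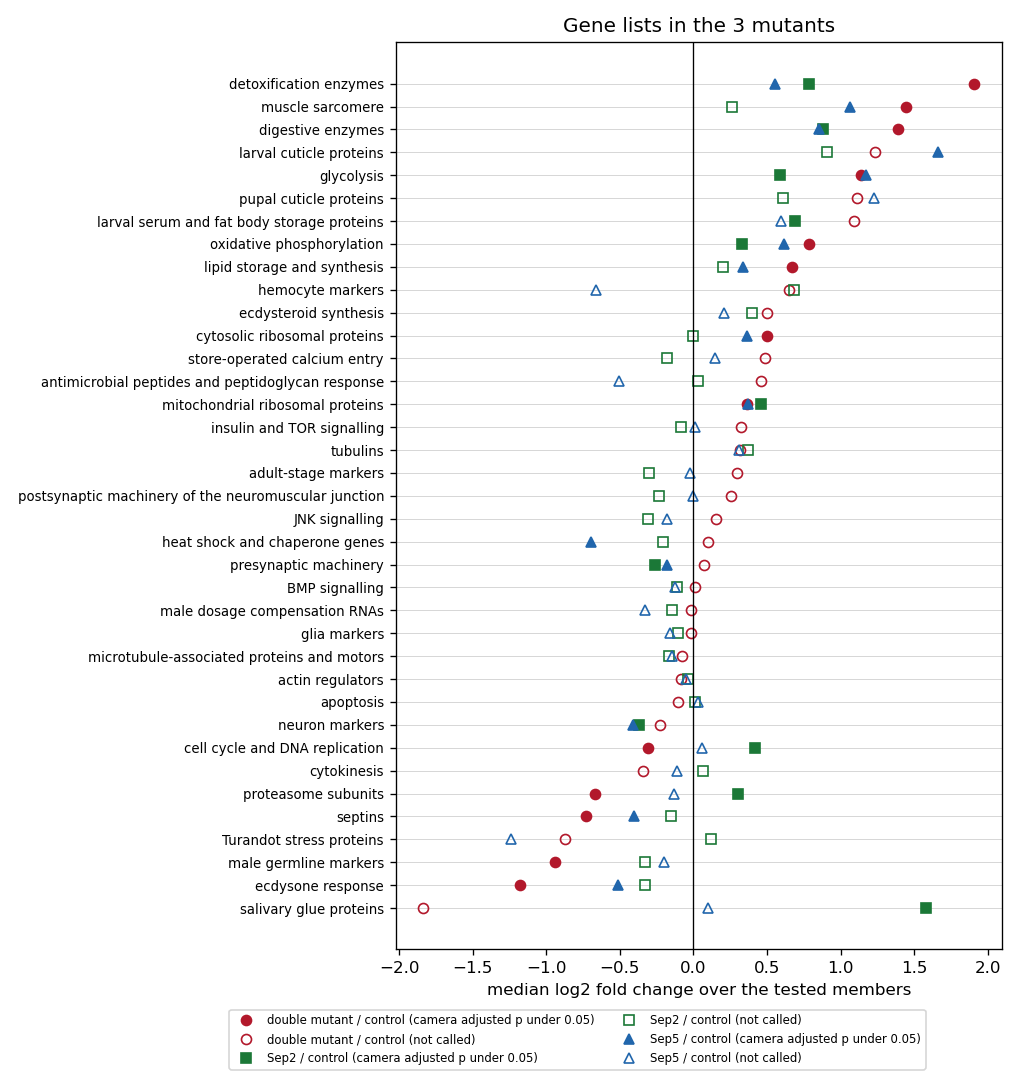
Median log2 fold change of each gene list for the 3 mutants against the control; filled symbols are lists past the camera threshold with the preset correlation, none of which passes with an estimated one. In the double mutant oxidative phosphorylation and muscle sarcomere lie above 0 and the ecdysone response below; medians of tubulins and heat shock genes in the double mutant and of tubulins and glue proteins in the Sep5 mutant change sign under quantile normalization, as do some nearer 0 under other scalings.

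**Figure D4:**
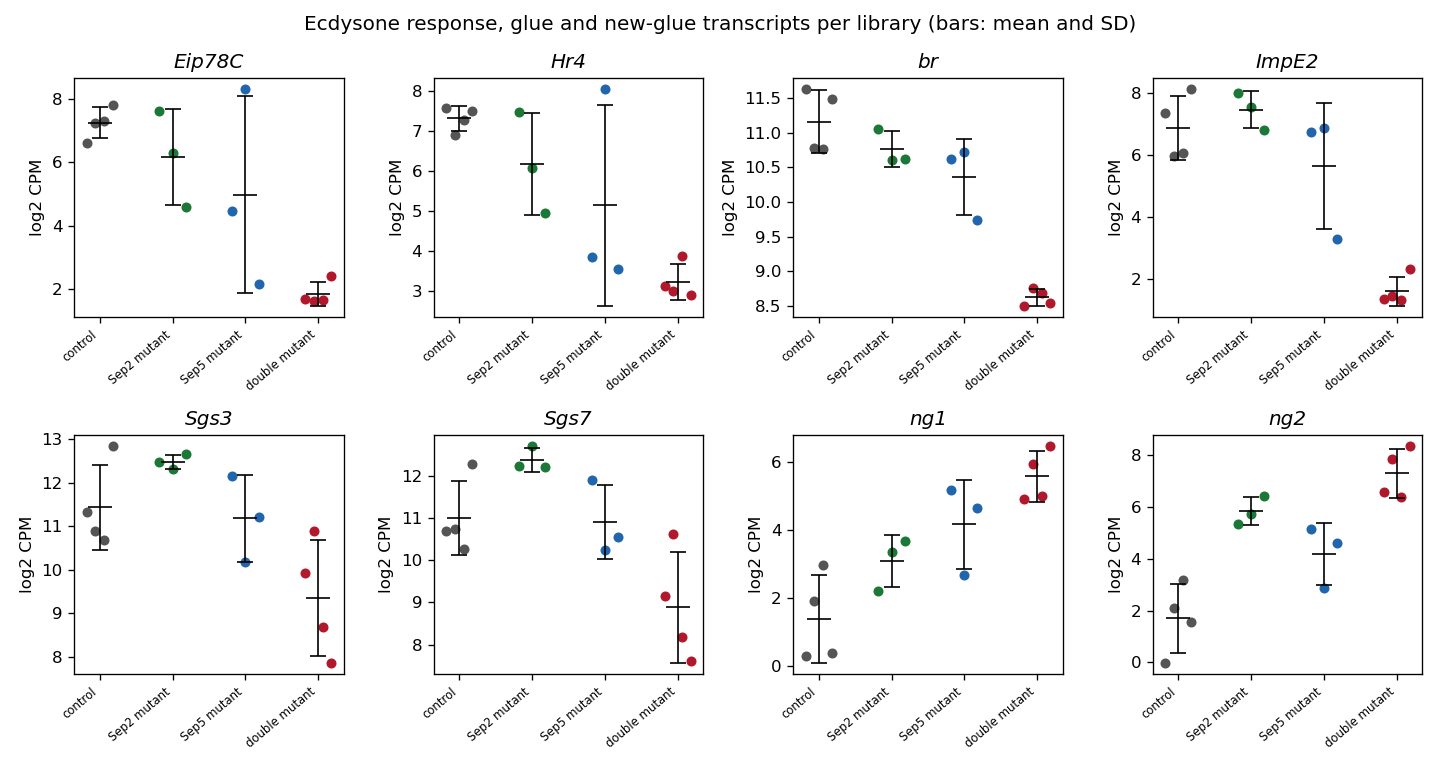
Level of 4 ecdysone response genes, 2 glue genes and 2 new-glue genes in each of the 14 libraries in log2 CPM, by genotype; points are libraries and bars give the mean and SD. In the double mutant br and ImpE2 lie below the control and ng1 and ng2 above it.

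The remaining lists were not called in the double mutant. The hemocyte genes Pxn, which encodes peroxidasin (1.39), Sr-CI, a scavenger receptor (1.59), and the collagen gene vkg (1.20) rose. Hemocyte markers were not called, with 5 of 11 tested members higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.0530). Hemocyte markers were called without control replicate 1 (0.0308), Sep5 mutant replicate 3 (0.0461) or Sep2 mutant replicates 2 (0.0352) or 3 (0.0454), within an adjusted p of 0.0308 to 0.0881 over the alternatives. The immune genes BomBc3 (3.18) and AttA (3.59) rose. The immune list was not called, with 5 of 24 tested members higher and 1 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.239). The ecdysteroid gene shd rose (0.86). Ecdysteroid synthesis was not called, with 5 of 12 tested members higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.182). The insulin-like peptide gene Ilp3 rose (2.94). Insulin and TOR signalling was not called, with 5 of 17 tested members higher and 2 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.339). The calcium pump gene SERCA rose (1.31). Store-operated calcium entry was not called, with 2 of 5 tested members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.296). The storage protein gene Lsp1beta rose (1.30), though not after quantile normalization (0.454, within 0.00138 to 0.454 over the alternatives), and Fbp1 fell (-2.02). Larval serum and fat body storage proteins were not called, with 4 of 7 tested members higher and 1 lower (4 and 1 adjusted over the list alone, camera adjusted p = 0.372). The cuticle genes Lcp9 (2.16) and Edg78E (1.87) rose. Larval cuticle proteins were not called, with 5 of 14 tested members higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.103). Larval cuticle proteins were called without control replicate 3 (0.0192) or double mutant replicate 3 (0.0398), within an adjusted p of 0.0192 to 0.342 over the alternatives. Pupal cuticle proteins were not called, with 1 of 4 tested members higher and 1 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.696). With double mutant libraries 1 and 2 alone vkg and Fbp1 were not called.

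Among stress genes Hsp67Bc fell (-2.50). Heat shock genes were not called, with 2 of 16 tested members higher and 4 lower (2 and 4 adjusted over the list alone, camera adjusted p = 0.816). Turandot proteins were not called, with 0 of 3 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.895). In the nervous system Gad1, which makes GABA, rose (0.94), loco fell (-0.68) and the glial transcription factor gene repo rose (0.90). Neuron markers were not called, with 1 of 17 tested members higher and 1 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.735). Glia markers were not called, with 2 of 9 tested members higher and 2 lower (3 and 2 adjusted over the list alone, camera adjusted p = 0.950). The BMP receptor gene tkv fell (-0.93), and Ilp8 of the JNK list rose (1.76). BMP signalling was not called, with 0 of 13 tested members higher and 2 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.816). JNK signalling was not called, with 1 of 13 tested members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.931). The death gene hid fell (-1.34) and p53 rose (0.71). Apoptosis was not called, with 1 of 11 tested members higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.776). Actin regulators were not called, with 1 of 17 tested members higher and 2 lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.776). Adult-stage markers were not called, with 0 of 6 tested members higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.960). Male dosage compensation RNAs were not called, with 0 of 3 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.816). The median, the mean and the test differed in sign for heat shock genes, BMP signalling, glia markers, adult-stage markers and microtubule-associated proteins.

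The Sep2 mutant was compared with the control. Stock background and septin mutation go together in this design, so a change here need not come from the Sep2 mutation. The lysozyme genes LysD (9.72, SE 0.83, adjusted p = 1.45e-05), LysC (9.43), LysB (5.77) and LysE (5.64) rose. So did Cyp6a17 (7.09, SE 0.61, adjusted p = 8.32e-06) and CG13461 (5.81). Lower were CG12824 (-3.57), the antibacterial gene Listericin (-3.30), CG33346 (-2.89) and the photolyase gene phr (-2.66, SE 0.19, adjusted p = 2.22e-06). The serpin gene Spn42De (-2.53) and CG42650 (-2.53) also fell. Among list members, Cyp12d1-p (3.31), GstE3 (1.78) and GstE1 (2.28) of detoxification and ng2 (4.12) rose. The cuticle gene Edg78E (2.54), the replication gene PCNA (1.02), Cdk1 (0.92) and AttA (3.14) rose. In all, 566 genes changed, 410 higher and 156 lower. The count was 351 and 343 without control replicates 1 and 2, and 320, 351 and 312 without Sep2 mutant replicates 1, 2 and 3. It was 4091 with sample weights, in a fit that gave Sep2 mutant replicate 1 a weight of 9.75, and 46.1% of these were higher against 72.4%. Without control replicate 4 LysD stood at 10.73, LysC at 10.48 and Cyp6a17 at 7.85. CG42650 was not called without Sep2 mutant replicates 1 (0.0516) and 3 (0.0611), within an adjusted p of 1.07e-05 to 0.0611 over the alternatives.

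Mitochondrial ribosomal proteins were called higher in the Sep2 mutant, with 7 of 72 tested members higher and 0 lower (24 and 0 adjusted over the list alone, camera adjusted p = 3.09e-13). Digestive enzymes were called higher, with 12 of 46 tested members higher and 1 lower (24 and 5 adjusted over the list alone, camera adjusted p = 9.84e-09). Detoxification enzymes were called higher, with 6 of 18 tested members higher and 0 lower (10 and 1 adjusted over the list alone, camera adjusted p = 3.85e-05). Cell cycle and DNA replication was called higher, with 4 of 24 tested members higher and 0 lower (9 and 0 adjusted over the list alone, camera adjusted p = 0.000402). Each of these 4 lists had an adjusted p of 0.378 with an estimated correlation. Salivary glue proteins were called higher, with 1 of 10 tested members higher and 0 lower (7 and 0 adjusted over the list alone, camera adjusted p = 0.000786). Their adjusted p was 0.722 with an estimated correlation. Oxidative phosphorylation was called higher, with 2 of 83 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 3.85e-05). Proteasome subunits were called higher, with 0 of 30 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.00366). Glycolysis was called higher, with 0 of 13 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0136). Neuron markers were called lower, with 0 of 17 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.00329). With an estimated correlation these 4 lists had an adjusted p of 0.769. Neuron markers were not called without Sep2 mutant replicate 2 (0.0752), within an adjusted p of 0.000227 to 0.0752 over the alternatives. Glycolysis was not called without control replicate 4 (0.163) or Sep2 mutant replicate 3 (0.281), within an adjusted p of 0.000110 to 0.281 over the alternatives. Nuclear ribosomal RNA, which moved with these groups, took a mean of 1.88% of the reads of the Sep2 mutant (SD 0.649, n = 3) and 0.864% of those of the control (SD 0.343, n = 4), without overlap.

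The presynaptic list was called lower in the Sep2 mutant, with 1 of 27 tested members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.0499). It had an adjusted p of 0.769 with an estimated correlation. The presynaptic list was not called without control replicates 1 (0.0709) and 4 (0.252), double mutant replicates 1 (0.0508), 2 (0.0505) and 3 (0.0533), Sep5 mutant replicates 1 (0.0559) and 2 (0.0617) or Sep2 mutant replicates 1 (0.0610) and 2 (0.361), nor with the replicate block (0.176), after quantile normalization (0.0825), after centring on the median (0.0617) or with double mutant libraries 1 and 2 alone (0.0502), within an adjusted p of 0.00293 to 0.361 over the alternatives. Its 1 called member, Syt4, was higher (0.82, SE 0.21, adjusted p = 0.0369). Syt4 was not called without control replicates 1 (0.0569), 2 (0.1004) and 3 (0.0821), double mutant replicate 3 (0.0517) or Sep2 mutant replicates 1 (0.132) and 3 (0.152), nor without a filter (0.0593), after centring on the median (0.0827), with only the libraries of both groups (0.0702) or with double mutant libraries 1 and 2 alone (0.0621), within an adjusted p of 3.73e-05 to 0.152 over the alternatives. Storage proteins of serum and fat body were called higher, with 0 of 7 tested members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.0499). They had an adjusted p of 0.722 with an estimated correlation. The storage proteins were not called without control replicates 1 (0.0904) and 2 (0.0903), double mutant replicates 1 (0.0508) and 3 (0.0533), Sep5 mutant replicates 1 (0.0559) and 2 (0.0617) or Sep2 mutant replicates 1 (0.0610), 2 (0.0619) and 3 (0.0551), nor after quantile normalization (0.108), within an adjusted p of 0.0208 to 0.108 over the alternatives. Both lists also moved with nuclear ribosomal RNA. The postsynaptic list was not called, with 0 of 24 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0516). The postsynaptic list was called under the stricter filter (0.0396), with double mutant libraries 1 and 2 alone (0.0457) and without control replicate 2 (0.0165), double mutant replicate 4 (0.0439), Sep5 mutant replicate 3 (0.0466) or Sep2 mutant replicate 3 (0.00441), within an adjusted p of 0.00441 to 0.357 over the alternatives. Microtubule-associated proteins and motors were not called, with 1 of 29 tested members higher and 0 lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.0674). Microtubule-associated proteins and motors were called under the stricter filter (0.0488) and without control replicates 2 (0.0223) or 3 (0.0208) or Sep2 mutant replicate 3 (0.0186), within an adjusted p of 0.0186 to 0.361 over the alternatives. Both tests pointed lower. Pupal cuticle proteins were not called, with 1 of 4 tested members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.0715). Pupal cuticle proteins were called without control replicate 1 (0.0378), within an adjusted p of 0.0378 to 0.480 over the alternatives. The ecdysone response was not called, with 1 of 20 tested members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.272). The muscle sarcomere was not called, with 0 of 22 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.270). The muscle sarcomere was called without control replicate 3 (0.0110) or Sep2 mutant replicate 2 (0.0297), within an adjusted p of 0.0110 to 0.855 over the alternatives. Cytosolic ribosomal proteins were not called, with 1 of 91 tested members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.795). Cytosolic ribosomal proteins were called with the replicate block (0.0457), within an adjusted p of 0.0457 to 0.875 over the alternatives. Hemocyte markers were not called, with 0 of 11 tested members higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0674). Hemocyte markers were called with the replicate block (0.0455) and without control replicate 1 (0.0243) or Sep2 mutant replicate 2 (0.00271), within an adjusted p of 0.00271 to 0.281 over the alternatives. Median, mean and test differed in sign for Turandot proteins, cytosolic ribosomal proteins and insulin and TOR signalling, none of them called in the Sep2 mutant.

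The Sep5 mutant was compared with the control in the same way. The trypsin gene epsilonTry (chromosome 2R, 11345237 to 11346066) fell by a log2 fold change of -10.65, SE 0.36, adjusted p = 4.24e-10, betaTry by -4.89 and Alp7 by -8.09. Further decreases were in phr (-2.93), Listericin (-2.61) and CG33667 (-2.30). Cyp6a17 rose by 7.57, SE 0.61, adjusted p = 6.14e-06, and LysD by 7.24, SE 0.83, adjusted p = 0.000206. The genes LysC (6.86), CG13461 (5.71), LysE (4.61) and CG15534 (4.42) rose. The detoxification genes Cyp12d1-p (2.63), Cyp6w1 (2.60) and GstE1 (2.36) and the cuticle gene Lcp9 (2.63) rose, Lcp9 not with sample weights (0.0548, within 2.95e-05 to 0.0548 over the alternatives). In all, 646 genes changed, 490 higher and 156 lower. This count rested on single libraries, being 371 and 392 without control replicates 1 and 4, and 294, 1373 and 238 without Sep5 mutant replicates 1, 2 and 3. It was 350 with only the libraries of both groups. Without control replicate 4 LysD stood at 8.25, LysC at 7.91 and Cyp6a17 at 8.32. The mean level of the ecdysone list differed among the Sep5 mutant libraries, at 5.77, 6.47 and 4.99 log2 CPM in replicates 1, 2 and 3. The control lay between 6.12 and 6.71.

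Oxidative phosphorylation was called higher in the Sep5 mutant, with 13 of 83 tested members higher and 0 lower (48 and 0 adjusted over the list alone, camera adjusted p = 1.21e-11). Mitochondrial ribosomal proteins were called higher, with 2 of 72 tested members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 2.59e-09). The muscle sarcomere was called higher, with 3 of 22 tested members higher and 0 lower (16 and 0 adjusted over the list alone, camera adjusted p = 5.32e-08). Glycolysis was called higher, with 6 of 13 tested members higher and 0 lower (12 and 0 adjusted over the list alone, camera adjusted p = 5.32e-08). Digestive enzymes were called higher, with 11 of 46 tested members higher and 3 lower (21 and 4 adjusted over the list alone, camera adjusted p = 5.32e-08). Larval cuticle proteins were called higher, with 2 of 14 tested members higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.000139). Detoxification enzymes were called higher, with 3 of 18 tested members higher and 0 lower (4 and 0 adjusted over the list alone, camera adjusted p = 0.00364). Each of these 7 lists had an adjusted p of 0.493 with an estimated correlation. Cytosolic ribosomal proteins were called higher, with 0 of 91 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 1.26e-07). Their adjusted p was 0.561 with an estimated correlation and 0.108 after quantile normalization, within 4.01e-09 to 0.108 over the alternatives.

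Neuron markers were called lower in the Sep5 mutant, with 0 of 17 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.00568). The ecdysone response was called lower, with 0 of 20 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.00620). Both had an adjusted p of 0.561 with an estimated correlation. The ecdysone response was not called without Sep5 mutant replicate 3 (0.0866), within an adjusted p of 0.000287 to 0.0866 over the alternatives. The septins were called lower, with 0 of 5 tested members higher and 1 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.00644). Septin5 was the member past the threshold, and the adjusted p was 0.493 with an estimated correlation. Lipid storage and synthesis was called higher, with 0 of 13 tested members higher and 0 lower (5 and 0 adjusted over the list alone, camera adjusted p = 0.0159). Its adjusted p was 0.493 with an estimated correlation. Lipid storage and synthesis was not called without control replicate 2 (0.0581) or Sep5 mutant replicate 3 (0.0507), within an adjusted p of 0.00700 to 0.0581 over the alternatives. Heat shock genes were called lower, with 0 of 16 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0322). Their adjusted p was 0.680 with an estimated correlation. Heat shock genes were not called without control replicates 1 (0.103) and 4 (0.164) or Sep5 mutant replicates 2 (0.0724) and 3 (0.0843), within an adjusted p of 0.00107 to 0.188 over the alternatives. The presynaptic list was called lower, with 0 of 27 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0399). It had an adjusted p of 0.591 with an estimated correlation. The presynaptic list was not called without control replicates 1 (0.112) and 4 (0.166) or Sep5 mutant replicates 1 (0.0906) and 2 (0.0891), nor after quantile normalization (0.110) or after centring on the median (0.0628), within an adjusted p of 0.00943 to 0.166 over the alternatives. Median, mean and test differed in sign for the postsynaptic list, adult-stage markers, apoptosis and insulin and TOR signalling, none of them called in the Sep5 mutant.

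The double mutant was set against the Sep2 mutant, which by label differs in the Sep5 mutation. Septin2 was lower in the double mutant, at 0.350 to 9.19 against a mean of 25.8 CPM in the Sep2 mutant. The comparison therefore does not isolate the Sep5 mutation. Spn42De rose by 5.15, SE 0.33, adjusted p = 1.28e-06, as did CG7881 (4.53), CG42399 (4.47), CG12824 (4.43) and CG4716 (4.33). Alp7 (-9.09, SE 0.67, adjusted p = 5.97e-06), Achl (-7.11), Drsl5 (-6.86), CG34296 (-6.55) and CG34193 (-6.50) fell. In all, 3640 genes changed, 2016 higher and 1624 lower. The count was 2113 and 2017 without Sep2 mutant replicates 1 and 2, and 6807 with sample weights. CG34193 was not called without double mutant replicates 1 (0.0527), 2 (0.0642) and 3 (0.0628) or Sep2 mutant replicates 1 (0.124) and 2 (0.113), nor without a filter (0.0650), with 1 CPM added (0.0717), by voom (0.174) or with double mutant libraries 1 and 2 alone (0.103), within an adjusted p of 0.000233 to 0.174 over the alternatives. Drsl5 was not called with double mutant libraries 1 and 2 alone.

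Against the Sep5 mutant, which by label differs in the Sep2 mutation, epsilonTry was higher in the double mutant (7.87, SE 0.36, adjusted p = 2.96e-08). So were CG11893 (4.40) and CG42399 (4.37), the Integrator subunit gene IntS12 (4.37) and hgo (4.36). Lower were Drsl2 (-9.10, SE 1.04, adjusted p = 0.000212), CG3397 (-6.32), CG11892 (-5.86), Septin2 (-5.68) and CG34296 (-5.25). In all, 1121 genes changed, 649 higher and 472 lower. The count was 406 without Sep5 mutant replicate 2.

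Between the single mutants, epsilonTry (11.98, SE 0.39, adjusted p = 2.05e-10), Alp7 (9.43), betaTry (5.76), CG11893 (4.95) and IntS12 (3.13) were higher in the Sep2 mutant. Lower there were CG12824 (-4.17), CG4716 (-3.84), Spn42De (-3.57), the P450 gene Cyp6t3 (-3.16) and CG18417 (-2.98). In all, 306 genes differed, 142 higher and 164 lower in the Sep2 mutant. That count was 200 and 157 without Sep5 mutant replicates 1 and 3, 155, 177 and 198 without Sep2 mutant replicates 1, 2 and 3, and 1844 with sample weights. The share higher in the Sep2 mutant was 46.4%, and 38.8% to 58.0% over the alternatives, with 50.2% without control replicate 2, 51.0% without double mutant replicate 1, 58.0% without Sep5 mutant replicate 1, 54.1% without Sep5 mutant replicate 3 and 54.2% without Sep2 mutant replicate 1. CG4716 was not called without Sep5 mutant replicate 3 (0.0690) or Sep2 mutant replicates 1 (0.0588) and 2 (0.0667), nor without a filter (0.0564), within an adjusted p of 8.90e-05 to 0.0690 over the alternatives. CG18417 was not called without Sep5 mutant replicate 3 (0.154) or Sep2 mutant replicates 1 (0.135) and 3 (0.105), nor without a filter (0.0916), with only the libraries of both groups (0.125) or with double mutant libraries 1 and 2 alone (0.0506), within an adjusted p of 0.000274 to 0.154 over the alternatives.

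Departures of the double mutant from the sum of both single mutant changes on the log2 scale were tested as an interaction. Higher than the sum were epsilonTry (6.53, SE 0.51, adjusted p = 1.41e-05), CG42399 (4.53), Listericin (4.53), Spn42De (4.11) and CG12824 (3.84). Lower were LysD (-6.78, SE 1.18, adjusted p = 0.00789), LysC (-6.70), Drsl2 (-6.18), CG11892 (-6.15) and Cyp6a17 (-6.09). LysD, LysC and Cyp6a17 were called higher and Listericin lower in all 3 mutants. A shared rise gives a negative value without interplay of septins, and a shared fall a positive one. The hemocyte genes Sr-CI (1.99) and NimC1 (2.51) lay above the sum and the division genes Cdk1 (-1.60), sti (-1.36) and PCNA (-1.37) below it. In all, 562 genes passed, 278 higher and 284 lower. The count was 278 and 313 without control replicates 2 and 3, 314 without double mutant replicate 3, 282 and 291 without Sep5 mutant replicates 1 and 2 and 227 and 226 without Sep2 mutant replicates 1 and 2. It was 2204 with sample weights. After centring on the median 272 were higher and 191 lower, and after quantile normalization 339 and 279. The share higher was 49.5%, and 42.4% to 58.7% over the alternatives. It was 54.4% without control replicate 1, 51.8% without control replicate 2, 55.7% without Sep5 mutant replicate 1 and 58.5% without Sep2 mutant replicate 3. Drsl2 was not called without control replicates 2 (0.0632) and 3 (0.0616), double mutant replicates 1 (0.0521) and 3 (0.0656), Sep5 mutant replicates 1 (0.0850) and 2 (0.0785) or Sep2 mutant replicates 1 (0.0665) and 2 (0.104), nor without a filter (0.0727), with 1 CPM added (0.0536), by voom (0.0920) or with double mutant libraries 1 and 2 alone (0.114), within an adjusted p of 7.30e-05 to 0.114 over the alternatives. PCNA was not called with double mutant libraries 1 and 2 alone.

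Proteasome subunits were called below the sum, with 0 of 30 tested members higher and 2 lower (0 and 17 adjusted over the list alone, camera adjusted p = 8.13e-10). Mitochondrial ribosomal proteins were called below the sum, with 0 of 72 tested members higher and 1 lower (0 and 10 adjusted over the list alone, camera adjusted p = 1.25e-08). Salivary glue proteins were called below the sum, with 0 of 10 tested members higher and 4 lower (0 and 5 adjusted over the list alone, camera adjusted p = 0.000865). The presynaptic list was called above the sum, with 1 of 27 tested members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 5.30e-05). Neuron markers were called above the sum, with 1 of 17 tested members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.000198). The postsynaptic list was called above the sum, with 1 of 24 tested members higher and 0 lower (2 and 0 adjusted over the list alone, camera adjusted p = 0.000865). Each of these 6 lists had an adjusted p of 0.595 with an estimated correlation. Cell cycle and DNA replication was called below the sum, with 0 of 24 tested members higher and 6 lower (0 and 14 adjusted over the list alone, camera adjusted p = 4.27e-09). Its adjusted p was 0.158 with an estimated correlation. The interaction takes in the Sep2 mutant, where nuclear ribosomal RNA took 1.37% to 2.61% of the reads against 0.432% to 1.17% in the control.

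Microtubule-associated proteins and motors were called above the sum, with 1 of 29 tested members higher and 0 lower (1 and 0 adjusted over the list alone, camera adjusted p = 0.0155). JNK signalling was called above the sum, with 0 of 13 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0155). Both had an adjusted p of 0.595 with an estimated correlation. Microtubule-associated proteins and motors were not called without control replicate 4 (0.0538), nor with the replicate block (0.0948) or after quantile normalization (0.157), within an adjusted p of 0.00325 to 0.157 over the alternatives. JNK signalling was not called without control replicate 4 (0.0538) or Sep5 mutant replicate 3 (0.0550), nor with the replicate block (0.115) or under the stricter filter (0.0665), within an adjusted p of 0.00344 to 0.115 over the alternatives. The ecdysone response was called below the sum, with 0 of 20 tested members higher and 1 lower (1 and 4 adjusted over the list alone, camera adjusted p = 0.0382). Its adjusted p was 0.691 with an estimated correlation. The ecdysone response was not called without control replicate 2 (0.105), double mutant replicate 1 (0.0878), Sep5 mutant replicate 2 (0.229) or Sep2 mutant replicate 1 (0.168), within an adjusted p of 0.000580 to 0.229 over the alternatives. Oxidative phosphorylation was called below the sum, with 0 of 83 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0382). Its adjusted p was 0.862 with an estimated correlation. Oxidative phosphorylation was not called without control replicates 1 (0.150) and 4 (0.427), double mutant replicates 2 (0.232) and 3 (0.0617), Sep5 mutant replicate 3 (0.262) or Sep2 mutant replicate 2 (0.132), nor with the replicate block (0.174), within an adjusted p of 0.000159 to 0.427 over the alternatives.

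Cytosolic ribosomal proteins were not called, with 0 of 91 tested members higher and 0 lower (0 and 0 adjusted over the list alone, camera adjusted p = 0.0997). Cytosolic ribosomal proteins were called with the replicate block (4.07e-06), with double mutant libraries 1 and 2 alone (6.24e-05) and without control replicates 1 (0.0343) or 4 (0.0159), double mutant replicate 4 (0.000298), Sep5 mutant replicate 1 (0.0304) or Sep2 mutant replicate 2 (0.00708), within an adjusted p of 4.07e-06 to 0.812 over the alternatives. The cytokinesis list was not called, with 0 of 17 tested members higher and 1 lower (0 and 1 adjusted over the list alone, camera adjusted p = 0.212). The cytokinesis list was called with the replicate block (0.0397), within an adjusted p of 0.0397 to 0.389 over the alternatives. Larval cuticle proteins were not called, with 0 of 14 tested members higher and 1 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.0530). Larval cuticle proteins were called with the replicate block (0.0431), under the stricter filter (0.0319), after quantile normalization (0.0414), after centring on the median (0.0265), with double mutant libraries 1 and 2 alone (0.0114) and without control replicates 2 (0.0490) or 3 (0.00180), double mutant replicate 4 (0.00368), Sep5 mutant replicate 2 (0.00869) or Sep2 mutant replicates 1 (0.0468) or 2 (0.00735), within an adjusted p of 0.00180 to 0.221 over the alternatives. Pupal cuticle proteins were not called, with 0 of 4 tested members higher and 1 lower (0 and 2 adjusted over the list alone, camera adjusted p = 0.0547). Pupal cuticle proteins were called with the replicate block (0.0474), after quantile normalization (0.0443), after centring on the median (0.0378), with double mutant libraries 1 and 2 alone (0.0353) and without control replicates 1 (0.0322) or 2 (0.0490) or 3 (0.0430), double mutant replicate 4 (0.0223), Sep5 mutant replicates 2 (0.0352) or 3 (0.0405) or Sep2 mutant replicate 2 (0.0391), within an adjusted p of 0.0223 to 0.245 over the alternatives. Of lists not called in the interaction, ecdysteroid synthesis, adult-stage markers and lipid storage and synthesis had a median, mean and test that differed in sign.

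Changes in the 3 mutants were compared across genes, which are not independent replicates, and all share the control libraries. Of the 646 genes called in the Sep5 mutant, 571 were called in the same direction in the double mutant, 452 higher and 119 lower. Independent lists give 110.3 and 35.0. Of the 566 called in the Sep2 mutant, 376 were, 273 higher and 103 lower. Independent lists give 92.3 and 35.0. The single mutants shared 182 genes, 135 higher and 47 lower, against 16.0 and 1.93. In 100 simulated sets of unchanged groups limma called a median of 0 genes in each mutant, so their overlap of 0 does not measure what shared controls add. At an unadjusted p under 0.05 the double and Sep5 mutants shared 2199 genes (simulated median 46, highest 722), the double and Sep2 mutants 1516 (44.5, highest 1946) and the single mutants 1066 (42, highest 648). Log2 fold changes of the double and Sep5 mutants correlated at r = 0.764 (rho = 0.779), of the double and Sep2 mutants at 0.571 (rho = 0.505) and of the Sep2 and Sep5 mutants at 0.584 (rho = 0.602). The simulated medians of r, with the range of the sets, were 0.446 (-0.202 to 0.895), 0.476 (-0.348 to 0.889) and 0.448 (-0.714 to 0.972), so each observed r lay inside that range. With the control libraries split between the comparisons r was 0.663, 0.475 and 0.443 on average. Covariances were 0.641, 0.447 and 0.285 against simulated medians of 0.0501, 0.0561 and 0.0579.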

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

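The tests of an intact Septin2 copy, of Septin5 reads assigned to Septin2, of whole chromosome arms, of the 1 Mb around each septin, of controls held out, of shares against single genotypes, of other splits of the libraries and of shuffled residuals were chosen after their results were seen. In the control, CG13606 stood at 5.66 log2 CPM in replicate 3 against 7.05 to 7.28 in the other libraries, far from its neighbour for the range of the group. This was so in 1 of 60 groups tested, and chance gives about 1 in 20. The other results are differences, by the interaction test, between the change from mutating Sep2 with and without the Sep5 mutation. This difference was 6.53 for epsilonTry, 4.53 for CG42399 and Listericin, 4.11 for Spn42De and 3.84 for CG12824. It was -6.78 for LysD, -6.70 for LysC, -6.18 for Drsl2, -6.15 for CG11892, -6.09 for Cyp6a17 and -4.58 for Septin2. As above, shared changes alone can give such values. The call for Drsl2 was lost in the runs given above, at an adjusted p of 7.30e-05 to 0.114 over the alternatives. That for Septin2 was lost without control replicates 2 (0.0639) and 3 (0.0592), double mutant replicates 1 (0.0607) and 3 (0.0649), Sep5 mutant replicates 1 (0.0786) and 2 (0.0703) or Sep2 mutant replicates 1 (0.0670), 2 (0.0884) and 3 (0.0578), at 1.26e-05 to 0.0884 over the alternatives.

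The mean of the 20 ecdysone response genes was 4.59 to 4.82 log2 CPM in the double mutant libraries and 6.12 to 6.71 in the control. Scaling is argued against as the cause, since the higher of the list medians after quantile normalization and after centring was -1.15. A candidate explanation is that the double mutant larvae were at an earlier stage of development when collected. In the 10 libraries of the other genotypes, gene slopes on the ecdysone level within a group correlated with the double mutant fold changes at r = -0.62 (rho = -0.63) over 12556 genes, which are not independent replicates, and 1 of 100 random lists was at least as negative, with a range from -0.64 to 0.68. Stage at collection, an effect of the mutations on stage or on hormone response, and any other factor that varies along the same axis between replicates all stay open.

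Septin2 lay about 1 log2 unit under the control in the Sep2 mutant and over 5 in the double mutant. Reads of Septin5 assigned to Septin2 are argued against, because Septin2 in the Sep5 mutant, which has 2 Septin5 reads, was 6.32 CPM above the control (SE 10.2), whereas the Sep2 mutant holds 25.8 CPM. An intact Septin2 copy in the Sep2 mutant larvae cannot be told apart from other sources of the remaining transcript, since over 13 genes of 3R the Sep2 mutant lay -0.27 log2 units (median, SE 0.39) from the value of a single changed copy, with single genes from -2.69 to 1.90. Double mutant replicate 4 held a median of 0.0113 of the lowest other genotype mean over 13 genes nearly absent in the group's other libraries. For Septin2 it was 0.354 (of the control mean 0.165 against 0.00569, of the Sep5 mutant mean 0.148 against 0.00809). This argues against RNA of another genotype of this series mixed in. As noticed afterwards, the highest shares were 0.310 for CG3397 and 0.110 for CG11892, both on 3R like Septin2. Then came 0.0531 for slbo of 2R and 0.0311 for CG13606 of 3R. What sets these genes apart stays open, as does RNA of other stocks.

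In all 3 mutants 168 genes changed in the same direction, 128 higher and 40 lower, and of such genes called against 2 of the controls, 89.8% to 100% lay the same way in all 3 mutants against the other 2 over 6 choices, which argues against chance values of shared controls as the whole cause. Sequence differences between the stocks are a candidate explanation for changed genes, tested with two-sided Fisher exact tests among 24 on location, and for the Sep2 mutant the odds ratio of a changed gene was 2.07 within 1 Mb of Septin2 (exact p = 0.00610, adjusted 0.0366), as differences near the gene would give, 1.35 within 2 Mb (exact p = 0.178, adjusted 0.305), 1.19 within 5 Mb (exact p = 0.228, adjusted 0.364) and 1.21 along 3R (exact p = 0.0510, adjusted 0.102), which leaves wider distances open. Between the double and the Sep5 mutant it was 1.51 along 3R (exact p = 2.82e-09, adjusted 6.76e-08) and 1.39 within 5 Mb of Septin2 (exact p = 0.00147, adjusted 0.0117), as differences along the arm would give, and between the double mutant and the control 1.12 along 3R (exact p = 0.00873, adjusted 0.0419). For the Sep5 mutant it was 0.866 within 2 Mb of Septin5 (exact p = 0.608, adjusted 0.664, upper bound 1.33), which argues against an excess over these 2 Mb as a whole, 1.22 within 1 Mb (exact p = 0.418, adjusted 0.521, upper bound 1.99), which leaves a nearer segment open, 1.37 within 5 Mb (exact p = 0.0263, adjusted 0.0700) and 1.66 along 2R (exact p = 5.95e-08, adjusted 7.14e-07), as differences along the arm would give, whereas 1.12 between the double and the Sep2 mutant (exact p = 0.0161, adjusted 0.0553) and 1.04 between the double mutant and the control (exact p = 0.434, adjusted 0.521) did not pass and leave this open for the step from the Sep2 to the double mutant. No other arm was tested, so no excess is shown to be particular to its arm, and neighbouring genes were taken as independent. Stock and septin mutation go together here, so an effect of the septins, untested, also stays open.

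Other splits of the same libraries into groups of the same sizes tested whether chance can give as many genes. For the double mutant against the control, 1 of 35 splits, the real one, gave 5658 genes, and the highest other gave 0. The real split was also the 1 of 35 with most genes for the Sep5 mutant (646, highest other 405). So it was for the double against the Sep2 (3640, 458) and the Sep5 mutant (1121, 77). Chance is argued against for these 4, but 1 of 35, uncorrected, cannot exclude it. For the Sep2 mutant the real split gave 566 genes, as the 1 of 35 with the most, and the highest other 74. Its replicate numbers were taken, from correlations alone, to pair it with the control. The real split was the 1 of 8 that part all 3 pairs with the most genes, where the highest other gave 19. Splits that part fewer pairs gave up to 74, and those that part all pairs are too few for a share under 0.05. For the Sep2 against the Sep5 mutant, 10 splits are too few for a share under 0.05, and the real count was 306 and the highest other 13. For the interaction 2 of 100 arrangements gave as many as 562 genes, the other of these 5385, which points to a structure of the samples. That arrangement set the 4 double mutant libraries and 2 of the 3 Sep5 mutant libraries against the rest. Such shuffles put the effects of the mutations into the spread, so they do not bear on chance for a departure from the sum. With the residuals of a fit without the interaction shuffled over the libraries and added back, 1 of 100 arrangements, the real one, gave 562 genes and the highest other 210, so chance spread around the sum is argued against for the count.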

How the results depend on the processing

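Double mutant libraries 1 and 2 alone and median centring of list tests were chosen after the data were seen. Counts of genes beyond 1.5 times that of the report follow, and the cause was not tested except where the setting itself removes genes or samples. Sample weights gave 4091 for Sep2 against control, 6807 for double against Sep2, 1844 for Sep2 against Sep5 and 2204 for the interaction. Only the libraries of both groups gave 350 for Sep5 against control, 631 for double against Sep5 and 187 for Sep2 against Sep5. The stricter filter gave 200 for Sep2 against Sep5, and a 2-fold minimum 3515 for double against control and 2129 for double against Sep2. Double mutant libraries 1 and 2 alone gave 1756 for double against Sep2, 405 for double against Sep5 and 203 for the interaction. Leaving out one library at a time gave 4812 to 5708 for double against control, 312 to 617 for Sep2, 238 to 1373 for Sep5, 2017 to 3793 for double against Sep2, 406 to 1195 for double against Sep5, 155 to 342 for Sep2 against Sep5 and 226 to 613 for the interaction. The correlation of effects with split controls was 0.475 for double and Sep2, 0.663 for double and Sep5 and 0.443 for Sep2 and Sep5, and 0.795 for double and Sep5 under the stricter filter. Leaving out one library at a time gave 0.424 to 0.627, 0.683 to 0.805 and 0.485 to 0.635 for these pairs. Of called values of named genes, 1 turned sign, betaTub56D in double against control, called at 0.50 and at -0.045 after quantile normalization (adjusted p = 0.846, over all alternatives 0.0275 to 0.846), and its call was lost without control replicates 1 (0.0854), 2 (0.140) and 4 (0.0544), double mutant replicates 1 (0.0734), 2 (0.0777), 3 (0.0726) and 4 (0.0868), Sep5 mutant replicate 3 (0.0561) or Sep2 mutant replicate 1 (0.0620), and after centring on the median (0.0547), with only the libraries of both groups (0.0706) and with double mutant libraries 1 and 2 alone (0.156). Of 16655 values of named genes under an alternative, 15737 kept their side of the threshold, 597 lost a call, 320 gained one and 1 called value turned sign. Changes of sign were counted for called values only, so uncalled values can have changed sign among the 15737 and the 320. Signs of list medians are not counted here. Of 2952 for gene lists, 2728 kept their side of the threshold, 120 lost a call, 49 of them with an estimated correlation, and the others gained one. Outside the control and the Sep2 mutant, shared replicate numbers were not taken as pairs. Over all groups 19 pairs correlated from -0.40 to 0.45, 8 above 0.1, and 5 of 14 libraries correlated best with their own number. With the replicate block there were 5706 genes for double against control, 528 for Sep2, 592 for Sep5, 3477 for double against Sep2, 1105 for double against Sep5, 336 for Sep2 against Sep5 and 440 for the interaction. In the Sep2 mutant against the control the block ended the calls of Cth, mRpL30, mRpS16, geminin, RnrL and presynaptic machinery, added those of chb, Lsd-1, hemocyte markers and cytosolic ribosomal proteins, and changed no other call of a named gene or list. In the interaction it ended those of tau, Nlg1, Rdl, Sgs8, Sgs5, Sgs7, Lcp3, Rpn12, Prosbeta3, mRpL30, CycA, microtubule-associated proteins and motors, oxidative phosphorylation and JNK signalling, added those of HDAC6, ImpE1, Pcp, AkhR, cytokinesis, larval cuticle proteins, pupal cuticle proteins and cytosolic ribosomal proteins and changed no other. Depth limits low genes most in double mutant replicate 3.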

Other observations

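No test in this part was chosen after its result was seen. Insulin-like peptide genes were called in some mutants. Ilp3 rose in the double mutant (2.94, SE 0.23, adjusted p = 2.13e-06) and in the Sep2 mutant (1.66, SE 0.25, adjusted p = 0.00140) and stood at 0.90, SE 0.25, adjusted p = 0.0537 in the Sep5 mutant, where it was called after centring on the median (0.0492), without the intensity trend and robust shrinkage (0.0440) and with sample weights (0.0213), within 0.0213 to 0.214 over the alternatives. The Sep2 mutant lay 0.76 from the Sep5 mutant in Ilp3, SE 0.27, which did not pass the test (adjusted p = 0.188). Ilp8, a peptide that delays development, rose in the double mutant (1.76, SE 0.36, adjusted p = 0.00151). Among immune genes, BomBc3 lay above the sum of the single mutant changes (3.20, SE 0.47, adjusted p = 0.00271) and PGRP-SC2, which degrades peptidoglycan, below it (-2.68, SE 0.53, adjusted p = 0.0138).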
